A study of Arabidopsis thaliana with 3 samples.

How the data were processed

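The series holds 3 RNA-seq libraries of Arabidopsis leaves, 1 each for explants 2 days after wounding, a 2-day control and a control at the start (T0), as the treatment labels give them. The values used were the deposited read counts per gene, whole numbers that the authors had not normalized. The submitters' processing notes name FastQC, HTSeq and DESeq and the genome build TAIR10, with no role, order or version. The aligner, the annotation release, the strand setting and the library kit are not given in the sources used here. Without a stated strand setting, it is not known how reads in a stretch shared by overlapping genes were treated.

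Each table listed 33602 genes, of which 8455 had 0 counts in all libraries. Lines that name no gene were kept out of the totals: reads assigned to more than one gene made up 2.12% of the explant's assigned, ambiguous and unassigned reads, 2.18% of those of the 2-day control and 2.17% at T0, and reads in no gene 0.700%, 0.763% and 0.677%. Lines for reads not aligned or not uniquely placed held 0. All 279 organelle genes were listed at 0 in every library, so organelle shares could not serve as a sign of library quality. Totals were 46713257, 45097732 and 43099934 counts. The 10 most abundant genes held 2.08%, 2.22% and 3.06% of the counts and the 100 most abundant 11.0%, 11.5% and 15.8%. TMM factors were 1.08, 1.06 and 0.879, and the floor of 3 counts, set per library, was worth 0.0598, 0.0629 and 0.0792 CPM.

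Gene names came from the reference annotation of TAIR10.1, which is not the build named by the submitters, so none of its coordinates are given and it served for symbols, synonyms and overlaps or copies only. By locus tag 32835 of the 33602 genes matched, and 20088 of the 20109 past the filter, 8680 of these with a symbol. Reference sequences of 415 reported genes were searched against all genes with blastn at 95% identity over 100 bases, a limit set after a first look had missed known copies. Of these genes 16 had such a match: PHT1;1, LHCB1.1, LHCB1.2, LHCB1.3, RBCS2B, RBCS3B, PRR9, RVE7, ASB1, LHCA2, LDOX, CYCB1;2, WRKY40, FER4, ARR8 and CA1. For FER4 and CA1 the match was the gene model that overlaps them, so it is a shared stretch and not a separate copy. In 5, over 50% of the exon bases lay in another gene model as well: MYC2, F3H, PGIP1, ESB1 and MYB106. Counts of both kinds are uncertain.

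Counts were scaled by TMM in edgeR 4.0.16 under R 4.3.3. Genes with at least 30 counts summed over the 3 libraries were kept. For each of the 3 comparisons the ratio of scaled counts was given an exact Clopper-Pearson 95% interval from the binomial split of the gene's counts between both libraries, and a gene was called higher or lower where that interval lay wholly beyond 2-fold. No model test was run, because 1 library per group leaves no estimate of spread. Log2 ratios used a prior count of 0.5. Each list's median was set against 10000 random lists of the same size drawn within 20 bins of mean expression, as a description of these libraries. Overlaps were set beside 100 simulated draws of unchanged libraries, with Poisson error alone and with an assumed coefficient of variation of 20%. The other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, DESeq2 1.42.0 (size factors only) and blastn 2.17.0.

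The groups, the rule for calls, 22 gene lists, 9 marker lists, 16 gene families taken by symbol, 9 of the 11 alternatives and the rule for named genes were fixed before the data were examined. The rule names NAC1, CEP1 and CEP2; in each comparison the 8 genes higher and the 8 lower with a symbol whose nearer interval bound lay farthest from 1; and up to 2 higher and 2 lower members per list. It names 156 genes, of which the text gives values for a part. Genes without a symbol were passed over, 8 higher and 11 lower in the explant against the 2-day control, 5 and 4 against T0, and 0 and 3 for the 2-day control against T0. Other members of the lists, such as PAL1, WOX5, STM, CCA1 and the ferritin genes, and the genes drawn in the plots, were chosen after their values were seen, as were 6 further lists. The alternatives were DESeq2 size factors, total counts, no count filter beyond 1 count, a filter of 150 counts, limits of 1.5-fold and 4-fold, a 99.9% interval, thinning to the smallest library, a prior count of 5, TMM from the compared libraries alone, and scaling on genes outside the 100 most abundant.

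The calls were tested on simulated counts for 20109 genes in which 200 were changed. For the explant against the 2-day control the rule recovered 86.6% of genes changed 3-fold, 95.5% of those changed 4-fold and 95.5% of those changed 8-fold. Against T0 the shares were 83.6%, 98.5% and 100% for the explant, and 80.6%, 91.0% and 95.5% for the 2-day control. Each run made 0 false calls, and the intervals covered the simulated ratio for 95.5%, 95.6% and 95.5% of genes. The simulation held counting error only, which leaves little room for false calls at a 2-fold limit. Unchanged libraries drawn with the assumed coefficient of variation of 20% gave more. On average 64.5 genes were called higher and 66.5 lower in the explant against the 2-day control. Against T0 the counts were 62.0 and 63.7 for the explant, and 61.9 and 61.9 for the 2-day control. Left out were organelle genes, which were all at 0, and any statement on which part of the leaf a library came from.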

Results

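RNA from first-pair rosette leaves of Arabidopsis thaliana, accession Col-0, was sequenced in 3 libraries, 1 per group. All 3 are recorded at 12 days after sowing, T0 and day 2 alike. Whether this is the age at the start or at sampling is not known, so comparisons with T0 may also hold a difference in leaf age. The groups were leaf explants 2 days after wounding, a control taken at 2 days and a control taken at the start (T0). Explants were detached leaf pieces kept on a B5 medium that held no carbohydrate; from such pieces new roots can form at the cut. The series text speaks of the wound site and of the rest of the leaf, but the labels do not say which part each library holds, so the groups are named here by their treatment labels. The deposited gene counts summed to 46713257 in the explant, 45097732 in the 2-day control and 43099934 at T0, and 23909, 22476 and 22535 genes had at least 1 count. With 1 library per group there was no p-value, standard error or replicate check. A gene is called higher or lower where the exact 95% counting interval of its ratio between the libraries lay wholly beyond 2-fold, which compares these libraries and not the conditions. The intervals, given in brackets after each ratio, cover counting error only. They may be too narrow even for that, since reads without molecular identifiers are not independent molecules. Levels are given as CPM, counts scaled to a common library size. Where a library had 0 counts, the ratio is a lower bound set by a floor of 3 counts in that library, with the count of the other library taken as exact.

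The series title puts the question of whether a NAC transcription factor pathway acts on the cell wall in wounded explants. From what is known of the study, its genes are NAC1 and the CEP cysteine endopeptidases, with extensins, structural proteins of the cell wall, downstream; these names were picked by the study, so their directions are not independent evidence. NAC1 (AT1G56010) stood at 30.7 CPM in the explant, 22.3 CPM in the 2-day control and 3.11 CPM at T0. It was 9.87-fold higher in the explant than at T0 (8.18 to 12.0) and 7.16-fold higher in the 2-day control than at T0 (5.91 to 8.73). Between the explant and the 2-day control the NAC1 ratio was 1.38 (1.27 to 1.49), short of the 2-fold rule. CEP1 (AT5G50260) had 11, 3 and 1 counts in the explant, the 2-day control and at T0, and CEP2 (AT3G48340) had 8, 0 and 1, below the filter of 30 counts over the libraries. The CEP1 ratio of explant to 2-day control was 3.48 (0.920 to 19.4), so a difference was not detectable at this depth. CEP3 (AT3G48350) was 4.32 times lower in the explant than in the 2-day control (3.69 to 5.08). EXT1 (AT1G76930, EXT4 in the reference names) reached 2659 CPM in the explant, against 127 CPM in the 2-day control and 3.09 CPM at T0. EXT3 (AT1G21310) reached 1422, 38.1 and 0.924 CPM. In the explant over the 2-day control this made EXT1 20.9-fold higher (20.4 to 21.4) and EXT3 37.3-fold higher (35.6 to 39.1). Both were already higher in the 2-day control than at T0, EXT3 by 41.3-fold (29.6 to 59.4). The other 8 extensins on the list stayed below the count filter. All these values are RNA levels, which do not show the amount of extensin protein.

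**Figure D1:**
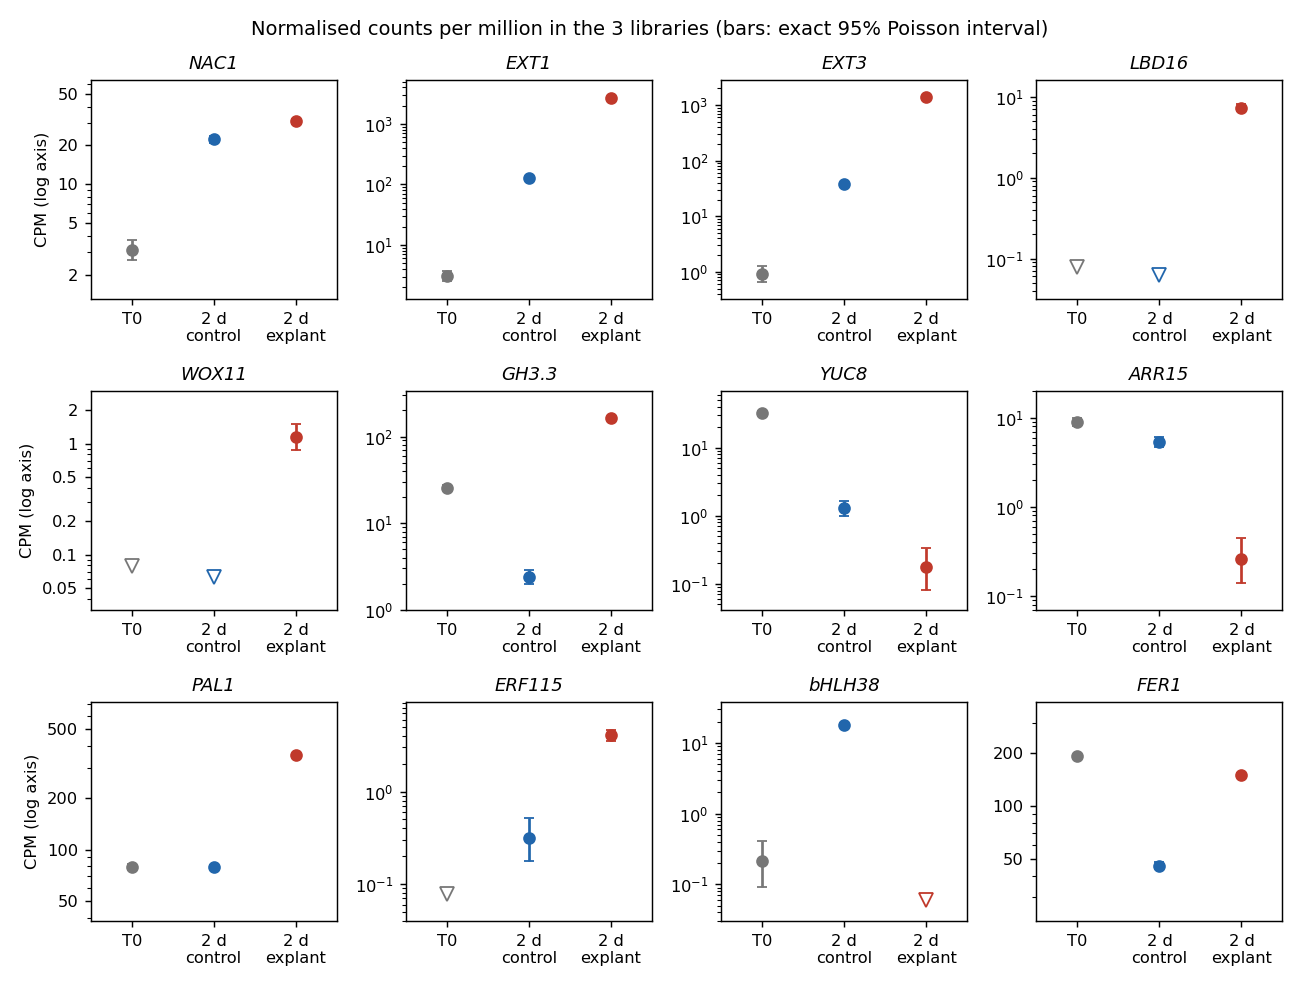
Normalised level in CPM (log axis, range set per panel) of 12 genes in the T0, 2-day control and 2-day explant libraries, 1 library each; bars are exact 95% Poisson intervals, mostly smaller than the points, and open triangles mark the 3-count floor of a library with 0 counts. NAC1 stands at 3.11, 22.3 and 30.7 CPM from left to right, while LBD16 was counted in the explant alone among these libraries, at 7.35 CPM.

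The explant was compared with the 2-day control to see how the libraries labelled as wounded and as control differ at the same day. The explant held transcripts of root founder cell regulators that had 0 counts in both controls, and higher levels of lignin precursor enzymes, wound-linked transcription factors, the nitrate transporter NRT2.1 and the phosphate transporters PHT1;1 and PHT1;4. LBD16, a target of auxin signalling in root initiation, had 369 counts against 0, at least 117-fold higher. PAL1, the entry enzyme of phenylpropanoid synthesis, was 4.48-fold higher (4.32 to 4.64). Lower in the explant were cytokinin response regulators, genes of auxin synthesis and 4 bHLH transcription factors that act in the response to iron deficiency. Of 20109 genes past the count filter, 2019 were higher and 1355 lower in the explant; 974 and 369 of them lay beyond 4-fold with their interval.

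The genes farthest past the rule on the higher side were FLS5 (AT5G63600), a member of the flavonol synthase family, PHT1;1 (AT5G43350), a phosphate transporter, the laccase LAC7, MYB45, the osmotin-like OSM34, WRKY61, the phloem lectin family member PP2-A3 and the root growth factor peptide gene RGF7. FLS5 had 6962 counts in the explant and 2 in the 2-day control, 3307-fold higher (915 to 27310). PHT1;1 was 864-fold higher (455 to 1889), a value that can include reads of the near-identical PHT1;2. LAC7 was 965-fold higher (376 to 3542). WRKY61 was counted 787 times against 0, at least 249-fold higher. On the lower side stood bHLH100 (AT2G41240), bHLH38, bHLH101, bHLH39, GASA6, the RADIALIS-like genes RL6 and RL5, and PAR1. The first of these had 0 counts in the explant and 946 in the 2-day control, at least 332 times lower. GASA6, a gibberellin-regulated gene, was 58.4 times lower (50.2 to 68.5), and PAR1, a gene of shade responses, 61.7 times lower (41.0 to 97.7).

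Among 12 measured regulators of root founder cells and primordia, 2 were higher, 1 was lower and 9 were neither. WOX11, which marks the first step from a leaf cell to a root founder cell, had 58 counts against 0 and was at least 18.4-fold higher, next to LBD16. WOX5 had 30 counts against 8, a ratio of 3.56 (1.60 to 8.99) that did not pass. The receptor kinase gene ACR4 was 2.58 times lower (2.28 to 2.91). The median log2 ratio of the list was -0.13 and its mean 1.18, of opposite sign. PLT1, PLT2, LBD29 and LBD33 were listed at 0 in every library. So was LHW, for which no overlapping gene model was found in the reference and the reason is not known. Of 15 auxin response genes, 5 were higher and 1 lower, with a median log2 ratio of 0.74 at percentile 99.99 of 10000 random lists matched on mean expression. The higher members included GH3.2, 229-fold (147 to 381), and GH3.3, 68.9-fold (57.3 to 83.7), both of which encode enzymes that conjugate auxin to amino acids. The lower member was IAA3. Auxin synthesis went the other way: 5 of 10 measured genes were lower and 1 higher, with a median of -1.27, below all 10000 random lists. YUC9 was 6.77 times lower (3.83 to 12.9) and YUC5 6.02 times (3.63 to 10.6), both flavin monooxygenases of the pathway, while ASB1, of tryptophan synthesis and with near-identical copies, was 2.63-fold higher (2.45 to 2.82). Of 12 cytokinin genes, 6 were lower and 0 higher (median -0.95, below all random lists). These were type-A response regulators, among them ARR16, 34.5 times lower (25.4 to 48.0), and ARR15, 20.6 times lower (11.8 to 39.2).

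Of 14 wound and stress transcription factors, 7 were higher and 1 lower. Their median log2 ratio in the explant was 0.10 against T0 (percentile 56.94) and 1.48 against the 2-day control, above all random lists. WRKY53 was 12.1-fold higher (10.4 to 14.1) and ERF115, known from cell replacement after damage, 12.9-fold (7.61 to 23.4); RAP2.6 was 6.95 times lower (2.70 to 22.8). The jasmonate list split, with 5 higher, 5 lower and 14 neither of 24 (median -0.40, percentile 0.87). The higher members were the defensin gene PDF1.2 at 47.6-fold (38.7 to 59.4), its regulator ORA59 at 6.94-fold (5.61 to 8.66), ERF1, and LOX4 and AOC3 of jasmonate synthesis. The lower members included VSP2, a vegetative storage protein gene, 7.80 times lower (7.11 to 8.59), and the repressor gene JAZ7, 6.10 times lower (4.33 to 8.80). Of 6 ethylene genes, 2 were higher and 0 lower, the synthase genes ACS2, 15.2-fold (8.29 to 31.0), and ACS6, 5.47-fold (5.06 to 5.92). Of 11 salicylate and camalexin genes, 2 were higher and 3 lower. PAD3, the last enzyme of camalexin synthesis, was 11.3-fold higher (9.68 to 13.3), and CYP71A13, an earlier enzyme of the same pathway, 2.95 times lower (2.57 to 3.41). Of the CYP71A13 exon bases 22.1% also lie in IMA3, an iron deficiency gene with log2 ratios to T0 of -3.51 in the explant and 3.0 in the 2-day control. With no strand setting given, reads in that stretch may have been set aside as assigned to more than 1 gene. How far this affects the CYP71A13 ratio is not known. Of 13 abscisic acid and dehydration genes, 8 were higher and 1 lower (median 2.13, above all random lists). RD29B was 36.1-fold higher (15.2 to 112) and the phosphatase gene HAI1 was among the others, whereas COR15A was 3.25 times lower (3.07 to 3.43). Of 14 senescence and sugar starvation genes, 6 were higher and 3 lower (median 1.09, above all random lists). WRKY6 was 6.61-fold (6.09 to 7.18) and the protease gene SAG12 8.55-fold higher (4.44 to 18.4), and ASN1, an asparagine synthetase induced by lack of sugar, 13.5 times lower (12.2 to 15.0).

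Of 17 phenylpropanoid and lignin genes, 12 were higher and 0 lower (median log2 ratio 1.57, above all random lists). CCR2 was 9.71-fold (7.42 to 12.9) and 4CL2 6.47-fold higher (5.88 to 7.14). The flavonoid list had 3 of 11 higher and 0 lower, among them FLS1 at 6.49-fold (5.20 to 8.19) and CHS; F3H, whose exons overlap another gene model, was listed at 0 throughout. Of 12 glucosinolate genes, 3 were higher, with CYP79F1 at 2.90-fold (2.72 to 3.09), and 1 was lower, CYP79B3, which did not pass with total counts. Of 19 cell wall enzyme and cellulose synthase genes, 2 were higher and 6 lower (median -0.96, below all random lists). The expansin gene EXPA10 was 3.97-fold higher (3.81 to 4.14), and the wall-remodelling enzyme gene XTH22 9.90 times lower (9.28 to 10.6). Of 27 cell cycle genes, 6 were higher and 0 lower (3 higher with an interval level stricter than 95%; median 1.01, above all random lists), led by the cyclin CYCD3;3 at 3.21-fold (2.81 to 3.68) and the kinase CDKB2;2 at 3.16-fold (2.61 to 3.85). Of 28 photosynthesis genes, 1 was higher, 2 were lower and 25 neither. LHCB1.4 was 22.5 times lower (21.5 to 23.5). LHCB1.1, which shares near-identical sequence with LHCB1.3, was 3.38-fold higher (3.16 to 3.63). The nitrate list had 3 of 5 higher, with the high-affinity transporter NRT2.1 at 271-fold (105 to 995) and the reductase NIR1 at 3.82-fold (3.76 to 3.89). Of 5 phosphate starvation genes, 2 were higher, both of them transporters, PHT1;1 and PHT1;4, the second at 29.2-fold (24.4 to 35.1). The low oxygen list had 1 of 7 higher (ADH1) and 2 lower (LBD41 and HRA1). None of the 10 clock genes passed in either direction, though the median log2 ratio of that list was 0.64, at percentile 99.38 of the random lists.

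Markers of other cell types were mostly neither higher nor lower between the explant and the 2-day control. In the phloem list 2 of 4 genes were lower, SUC2 by 2.24 times (2.17 to 2.30) and AHA3 by 2.06 times (2.01 to 2.12), the second of which did not pass with total counts. In the xylem list 1 of 8 was lower (CESA4, not with total counts), and in the epidermis list 1 of 6, ATML1 by 4.50 times (4.26 to 4.75). Of 3 procambium genes 1 was higher, WOX4. The 3 guard cell, 3 trichome and 2 stomatal lineage genes that could be measured passed in neither direction. No root hair or shoot meristem marker reached the count filter; the meristem gene STM had 20 counts in the explant and 0 in both controls.

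**Figure D2:**
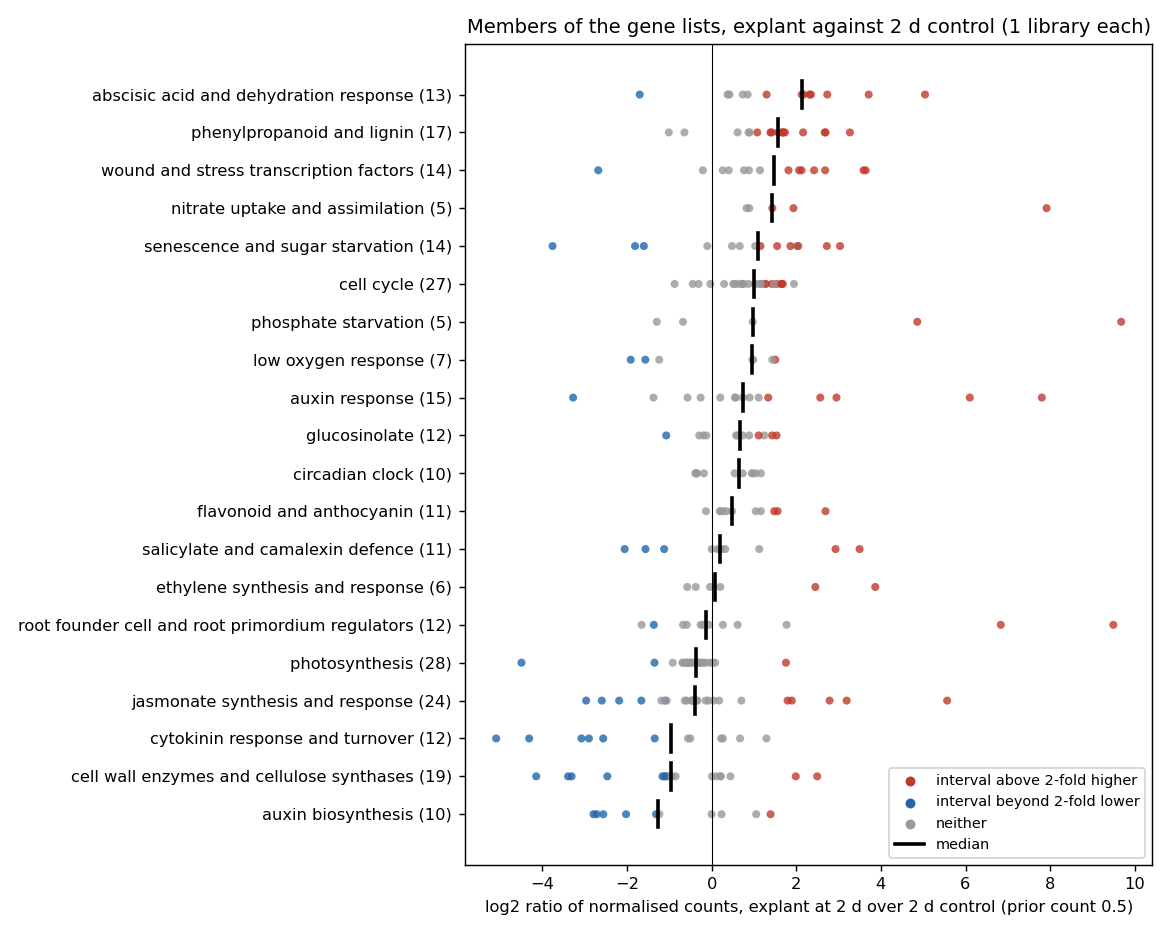
Log2 ratio of normalised counts in the explant over the 2-day control (1 library each, prior count 0.5) for each measured member of the gene lists; 1 point per gene, coloured by the 2-fold interval rule, with the list median as a black bar and the number of members in brackets. The phenylpropanoid list has 12 of 17 members on the higher side, and the cytokinin list 6 of 12 on the lower side.

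The explant was compared with T0 to follow the change from the starting leaf to the wounded piece. The extensins EXT1 and EXT3, the peroxidases Prx37 and PRX52 and 10 of 11 flavonoid genes were higher in the explant, and 21 of 28 photosynthesis and 9 of 12 cytokinin genes were lower. EXT3 was 1539-fold higher (1107 to 2210) and EXT1 861-fold (719 to 1042). Clock genes differed between the same libraries: 7 of 10 were lower in the explant and 1 was higher, with a median log2 ratio of -3.97; the hour of sampling is not in the labels. In all, 3570 genes were higher and 2681 lower. Of these calls 57.1% were higher, and 70.1% were with scaling by total counts. That scaling moved the median log2 ratio of all genes from 0.03 to 0.32 against T0, and ratios to T0 should be read relative to this shift.

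The genes farthest past the rule on the higher side were EXT3, FLS5, NIT2, Prx37, EXT1, PHT1;1, EARLI1 and PRX52. NIT2, a nitrilase, was 2703-fold higher (925 to 13108), and the peroxidase genes Prx37 and PRX52 were 1665-fold (765 to 4537) and 1315-fold (563 to 4051). On the lower side stood CIPK20, its neighbour DOG1, ASN1, TPS03, PAR1, GOLS3, LHCB2.3 and IAA29. CIPK20, a protein kinase, was 1193 times lower (511 to 3677), and ASN1 287 times (260.2 to 317). Of 28 photosynthesis genes 21 were lower and 1 higher (median log2 ratio -1.59, below all random lists). LHCB1.4 was 84.0 times lower (80.4 to 87.9) and LHCB2.2 72.4 times (68.0 to 77.1), while the RuBisCO small subunit gene RBCS1B was higher. Of 11 flavonoid genes 10 were higher and 0 lower. Their median of 6.01 lay above all random lists, and was 5.77 with the genes at 0 counts set to the floor. DFR, of anthocyanin synthesis, had 1476 counts in the explant and 1 at T0, a ratio of 1114 (199.7 to 44036). The phenylpropanoid list had 9 of 17 higher and 2 lower, CCR2 at 20.7-fold (13.5 to 33.3) against the lignin laccase gene LAC4, 11.7 times lower (9.48 to 14.6). Of 12 glucosinolate genes 9 were higher and 0 lower (median 1.55, above all random lists). Of 27 cell cycle genes 13 were higher and 1 lower (median 1.32, percentile 99.87), with the replication genes PCNA1 at 5.42-fold (4.53 to 6.54) and MCM2 at 4.53-fold (4.02 to 5.13).

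Most hormone lists had more members lower than higher in the same comparison. In auxin response 3 of 15 genes were higher and 8 lower (median log2 ratio -1.14, percentile 0.02): GH3.2 was 7.55-fold higher (6.86 to 8.33) and IAA29 203 times lower (128 to 344). In auxin synthesis 5 of 10 were lower, YUC8 by 182 times (95.4 to 398), and 1 was higher. In the cytokinin list 9 of 12 were lower, ARR15 by 34.9 times (20.1 to 66.1), and IPT3, of cytokinin synthesis, was 5.86-fold higher (4.98 to 6.94). The jasmonate list had 11 of 24 lower and 5 higher, CYP94B3 by 40.3 times lower (31.0 to 53.3) and PDF1.2 by 426-fold higher (216 to 987). Abscisic acid genes were 7 of 13 lower and 1 higher. Of 12 root regulators 5 were higher (2 at the filter of 150 counts) and 2 lower, LBD16 by at least 92.8-fold and WOX11 by at least 14.6-fold. Wound factors were 6 of 14 higher and 2 lower (median log2 ratio 0.10, percentile 56.94). RAP2.6L was 93.1-fold higher (48.9 to 204), and ERF109 was among the lower ones. Salicylate and camalexin genes were 4 of 11 higher and 0 lower, and PAD3 was 382-fold higher (149 to 1405). Senescence genes were 5 of 14 higher and 3 lower, nitrate genes 3 of 5 higher, phosphate genes 2 of 5 higher and 1 lower, and cell wall enzymes 5 of 19 higher and 8 lower. In the ethylene list 1 of 6 was higher (ACS2) and 1 lower (ACS8), and in the low oxygen list 2 of 7 were higher and 1 lower. Of the markers, 5 of 8 xylem, 3 of 6 epidermis, 2 of 4 phloem, 1 of 3 guard cell and 1 of 2 stomatal lineage genes were lower, and 1 of 3 procambium genes was higher.

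The 2-day control was compared with T0 to show how it differs from the starting leaf; whether it came from an uncut leaf is not in the labels. Flavonoid and anthocyanin genes were higher after 2 days, and most clock, photosynthesis, abscisic acid and auxin response genes were lower. Of 10 clock genes 7 were lower and 0 higher (median log2 ratio -4.30, below all random lists), with PRR9, which has a near-identical copy, 789 times lower (141 to 31214) and GI 96.5 times lower (84.1 to 111). The counts of higher and lower genes were 1748 and 1695. Of these calls 50.8% were higher, against 67.7% with total counts and 64.1% with scaling on genes outside the 100 most abundant, so the balance of directions hangs on the scaling. These moved the median log2 ratio of all genes from 0.04 to 0.31 and 0.25.

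Farthest past the rule on the higher side were the lectin gene JAL23, LURP1, THI2.1, DFR, LTP2, GSTF12, UF3GT and SAG13. JAL23 had 5005 counts against 2, a ratio of 1989 (550.2 to 16425). The thionin gene THI2.1 was 367-fold higher (193 to 802) and LURP1 327-fold (207 to 552). On the lower side stood CIPK20, DOG1, GOLS3, CBF2, PRR9, LHCB1.1, ddf2 and TPS03. CBF2, a cold response regulator, was 339 times lower (172 to 787), and DOG1, counted 960 times at T0 and 0 times after 2 days, at least 403 times lower. Of 11 flavonoid genes 9 were higher and 0 lower (median log2 ratio 5.52, above all random lists). Photosynthesis genes were 18 of 28 lower and 1 higher, and 12 of 13 abscisic acid genes were lower, RD29A by 48.8 times (46.2 to 51.6). Of 15 auxin response genes 10 were lower and 0 higher (median -2.94, below all random lists), GH3.2 by 30.3 times (19.2 to 50.9) and IAA29 by 77.3 times (57.6 to 106). Auxin synthesis was 5 of 10 lower, YUC8 among them, and 1 higher. Of 12 cytokinin genes 2 were higher, among them ARR16 at 9.58-fold (7.91 to 11.7), and 3 lower. Jasmonate genes were 5 of 24 higher, VSP1 by 15.0-fold (12.3 to 18.5), and 9 lower. Wound factors were 6 of 14 higher (3 with the stricter interval) and 6 lower (median -0.40, mean 0.32). RAP2.6L was 42.1-fold higher (22.0 to 92.7) and WRKY40 12.1 times lower (10.9 to 13.5). Glucosinolate genes were 4 of 12 higher and 0 lower, and MYB28, their regulator, was 5.76-fold higher (5.35 to 6.22). Salicylate genes were 5 of 11 higher and 1 lower, senescence genes 2 of 14 higher and 5 lower, and ethylene genes 2 of 6 lower. Phenylpropanoid genes were 1 of 17 higher (4 with total counts) and 4 lower, cell cycle genes 2 of 27 higher (5 with total counts) and 1 lower, cell wall enzymes 4 of 19 higher and 3 lower, and root regulators 1 of 12 higher and 1 lower. The low oxygen list had 2 of 7 higher and 1 lower, nitrate 1 of 5 each way, and phosphate 1 of 5 lower. Of the markers, 4 of 8 xylem, 2 of 6 epidermis and 1 of 3 guard cell genes were lower, trichome genes went 1 each way of 3, and no phloem, procambium or stomatal lineage gene passed. The only lower salicylate (PR5), phosphate (MGD3), root regulator (TMO5) and guard cell (KAT1) genes no longer passed with total counts.

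In the explant 1552 genes were higher and 942 lower than in both controls; some of these, such as EXT1 and EXT3, also differed between the controls. LBD16, WOX11, ERF115, EXT1, EXT3, GH3.2, PHT1;1, NRT2.1, PAL1 and CCR2 were among the higher genes, and YUC8, ARR15, ARR16, ATML1 and XTH22 among the lower ones. Independent lists of the same sizes would share 358 and 181 genes, and unchanged libraries simulated with an assumed coefficient of variation of 20% shared 3.19 and 9.16 on average. Both comparisons use the 1 explant library, so the lists are not independent. Anything particular to that sample enters both, and the excess does not show a response to the treatment. Against T0, the explant and the 2-day control shared 1353 higher and 1213 lower genes, where independent lists would share 310.3 and 226. The log2 ratios to T0 of the 2 libraries correlated across genes at r = 0.67, against 0.57 for simulated unchanged libraries with counting error alone; genes are not independent replicates. Their covariance was 1.62, against 0.019 in that simulation and 0.105 with the 20% variation, a difference of 1.61 and 1.52. Part of the excess may come from the shared T0 library, which cannot be divided into replicates. In opposite directions against T0 stood 71 genes, of which 46 were higher in the explant and lower in the 2-day control, such as GH3.2 and GH3.3, and 25 the reverse, such as bHLH38 and ARR16.

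**Figure D3:**
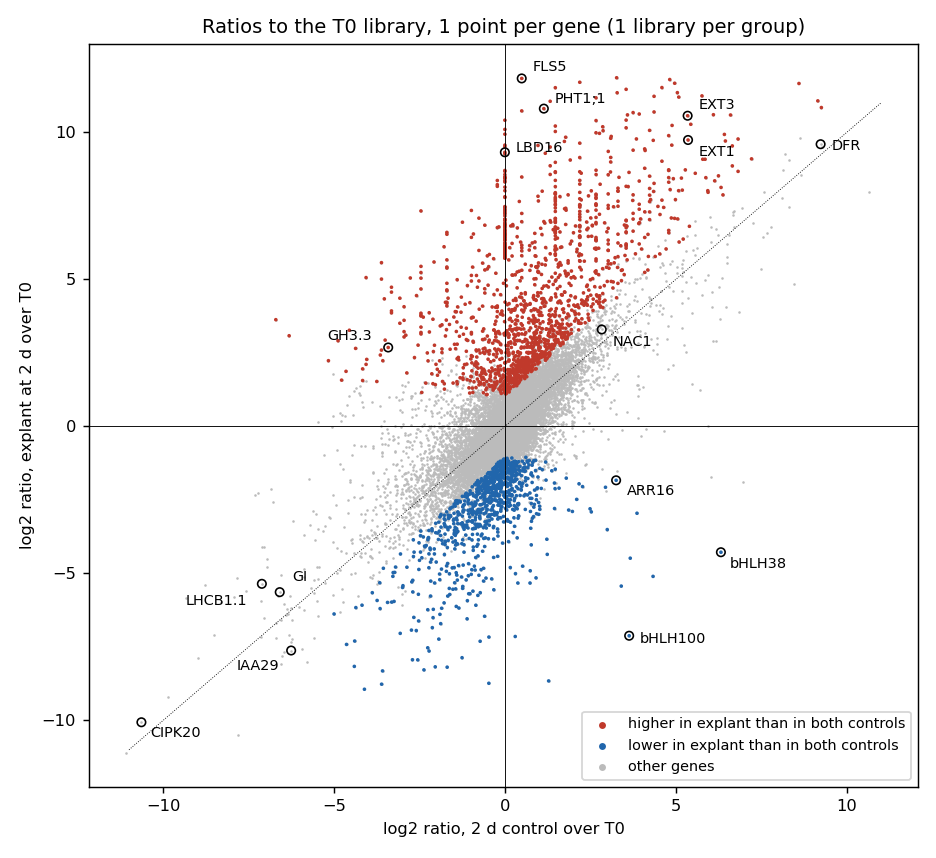
Log2 ratio to T0 of the explant (vertical) against that of the 2-day control (horizontal), 1 point per gene for 20109 genes and 1 library per group; the dotted line marks equal ratios, and vertical lines of points are genes with few or 0 counts in both controls. Red and blue mark the 1552 genes higher and the 942 lower in the explant than in both controls; bHLH38 and ARR16 lie at lower right, GH3.3 at upper left, and NAC1 near the line.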

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

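The iron gene lists, the test on summed bHLH counts and the comparison of ferritins with T0 were chosen only after the result was seen. Of the named genes and list members, 13 passed the 2-fold rule in opposite directions against T0 in the explant and in the 2-day control; the difference itself was not tested, since each group is 1 library. Values are log2 ratios to T0 with a prior count of 0.5, the explant first. GH3.2 stood at 2.92 and -4.88, GH3.3 at 2.69 and -3.41, HAI1 at 2.35 and -1.36, PR5 at 1.52 and -1.40, and WRKY53 at 1.16 and -2.43. With total counts the PR5 call in the 2-day control ended, so PR5 did not pass in opposite directions under that scaling. ARR16 stood at -1.83 and 3.26. The other 7 belong to the response to iron deficiency: bHLH38 at -4.28 and 6.32, bHLH100 at -7.12 and 3.64, bHLH101 at -8.66 and 1.28, IMA1 at -2.95 and 3.87, IMA2 at -4.48 and 3.67, IMA3 at -3.51 and 3.0, and NAS4 at -1.51 and 1.37. IMA3 shares 20.45% of its exon bases with other gene models, CYP71A13 among them. Reads there may have been set aside as assigned to more than 1 gene, so its counts are uncertain. The 3 bHLH genes had 0 counts in the explant, so their ratios depend on the prior count. By the 3-count floor, which takes the T0 count as exact and so overstates the bound where that count is small, as the 8 of bHLH38, they were at least 3.53, 26.5 and 77.3 times lower than at T0.

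Between the explant and the 2-day control, 13 of 14 iron deficiency genes were lower in the explant and 0 higher (median log2 ratio -4.75, below all random lists), while the 2-day control had 10 of them higher than T0. The list holds bHLH38, bHLH39, bHLH100 and bHLH101, whose low values in this comparison led to it. Its rank among random lists is therefore no support. Reads shared between similar family members are argued against as the cause, since the summed counts of bHLH38, bHLH39, bHLH100 and bHLH101 were 1 in the explant and 3038 in the 2-day control, 3198 times lower (574 to 126361). If more iron reached the explant from its medium, ferritins, which store iron, should be higher there, and 2 of 3 were higher than in the 2-day control, FER1 at 3.32-fold (3.16 to 3.48) and FER4 at 2.26-fold (2.12 to 2.41). Against T0, however, 0 of 3 were higher in the explant and 2 of 3 were lower in the 2-day control, with FER1 at 192 CPM at T0, 45.6 CPM in the 2-day control and 151 CPM in the explant, so the test does not separate more iron in the explant from less in the control. The labels give no iron content, and a difference between the leaf parts or in transport out of the leaf stays open and untested.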

How the results depend on the processing

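The alternatives with TMM from the compared libraries alone and with scaling on genes outside the 100 most abundant were chosen only after the results were seen. No paired analysis was possible because each group holds 1 library. Counts of higher and lower genes over all genes stayed within 1.5 times under every alternative except the other fold limits, which by construction call more or fewer genes. At 1.5-fold the explant had 3367 genes higher and 2692 lower than the 2-day control, and 4307 lower than T0; the 2-day control had 3180 and 2865 against T0. The explant then stood above both controls in 2629 genes and below in 1839, and both 2-day libraries above T0 in 2423 and below in 2173. At 4-fold these counts were 974 and 369 for explant against 2-day control, 1582 and 980 for explant against T0, 458 and 563 for 2-day control against T0, 776 and 254 against both controls, and 344 and 358 shared against T0. The correlation of ratios to T0 was 0.662 with total counts, 0.630 without the filter, 0.706 at 150 counts and 0.680 with a prior count of 5. The median log2 ratio of the expansin family (EXPA), explant against 2-day control, turned from -0.88 to 0.0916 with no count filter beyond 1 count, which adds genes near 0 counts; the cause was not tested. Of the list counts 324 moved by over 1.5 times and 2556 did not, most of the moves at the other fold limits. Root regulators higher in the explant than at T0 went from 5 to 2 at 150 counts, and cell cycle genes higher than in the 2-day control from 6 to 3 with the stricter interval level. In the 2-day control against T0, total counts took the higher cell cycle genes from 2 to 5 and the higher phenylpropanoid genes from 1 to 4. Another scaling shifts all genes alike, so list medians near 0 change sign by construction: with total counts this held for the ethylene, guard cell, root tissue and LBD lists in the explant against T0, and for the senescence and phloem lists in the 2-day control against T0. The ethylene median of the 2-day control against T0 kept its sign with total counts and changed it with DESeq2 size factors and with TMM from the compared libraries alone. No named call changed sign under the alternatives run. At 4-fold 49 of 77, 71 of 86 and 50 of 76 named calls still passed, in the order of the report. At the 2-fold limit total counts kept 74, 84 and 72 of them and the stricter interval level 71, 84 and 68; DESeq2 factors kept 74 of 77 in the first comparison. With total counts the calls of CESA4, CYP79B3 and AHA3 ended in the first comparison, those of CEP3 and AHA3 in the second, and those of KAT1, PR5, MGD3 and TMO5 in the third. Depth limits genes of few counts, such as CEP1 and CEP2.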

Other observations

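The cold, phase and root tissue lists, the look at the baseline of the root genes, and the scaling on genes outside the 100 most abundant, were chosen only after results were seen. Gene families taken by symbol gave a further view of the explant against the 2-day control. Of 51 measured WRKY genes 29 were higher and 2 lower, of 56 NAC genes 15 and 0, of 69 MYB genes 22 and 6, and of 21 ERF genes 8 and 0. Against T0 the explant had 28 WRKY genes higher and 2 lower, 20 and 4 NAC genes, and 29 and 11 MYB genes. ERF genes were 3 higher and 6 lower than at T0 in the explant, and 2 and 10 in the 2-day control. The ERF family was thus not raised over T0. The counts that follow are again for the explant against the 2-day control. Glutathione transferases, which detoxify reactive compounds, were higher in 11 of 23 GSTU and 5 of 11 GSTF genes, with 0 lower. Glycosyltransferases (UGT) were 13 of 46 higher and 2 lower, cytochrome P450 genes (CYP) 34 of 128 higher and 17 lower, and 3 of 3 peroxidase genes named PER or PRX were higher. Wall-loosening and wall-surface families leaned the other way: XTH had 5 of 23 higher and 10 lower, EXPA 1 of 14 higher and 4 lower (its median log2 ratio of -0.88 turned to 0.0916 with no count filter beyond 1 count), and the fasciclin-like arabinogalactan proteins (FLA) 1 of 14 higher and 6 lower. LBD genes were 4 of 14 higher and 2 lower. Ribosomal protein genes hardly passed, with 0 of 21 RPL and 1 of 23 RPS genes higher and 0 lower, and 2 of 20 HSP genes were higher.

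Cold response genes were lower in both 2-day libraries than at T0, 10 of 10 in each, with median log2 ratios of -4.11 in the explant and -5.40 in the 2-day control. This list was chosen after CBF2 and GOLS3 had been seen among the genes farthest lower than T0 in the 2-day control. Its count against T0 is therefore no independent support. Between the explant and the 2-day control 5 of 10 were higher and 2 lower: CBF1 was 8.18-fold higher (5.01 to 14.2), and COR15B, a target of the CBF regulators, 3.86 times lower (3.58 to 4.16).

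Of 10 clock genes 7 were lower than at T0 in each 2-day library. With total counts the list median in the 2-day control was -4.04. That test could not bring it near 0, since the scaling moved the median of all genes only from 0.04 to 0.31. The list stood at -4.30 where all genes had 0.04. Scaling shifts all genes alike and leaves that gap, which argues against it as the cause. Leaves collected at another hour than T0 could give the lower clock genes. In that case dawn-phased and midday to evening-phased genes move apart. Their median log2 ratios to T0 differed by 1.75 in the 2-day control and 2.37 in the explant. Both were past the limit of 1 set before the test. Against a plain shift of hour, 4 of 5 dawn-phased genes were themselves lower in each library, and CCA1 was 35.5 times lower (26.5 to 48.8) where LHY, its close partner at dawn, was 2.89-fold higher (2.25 to 3.76) in the explant. A further condition, that the phase groups do not overlap, was set after these values were seen, and with no hour in the labels the hour cannot be told apart from whatever else differs between T0 and day 2.

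The 1552 genes higher in the explant than in both controls may reflect the wound treatment, root tissue already present in the piece, or scaling by a few abundant genes. They may also reflect the part of the leaf each library holds, which the labels do not give, or detachment and culture on the medium. Scaling on genes outside the 100 most abundant gave 1639 genes, so the count did not rest on having those genes in the scaling. It cannot decide whether a few genes are the cause. The 100 genes held a minor share of the counts in every library, so leaving them out could change the ratios only a little. Root tissue stays open: of 10 root genes 4 were measured and 0 were higher than in both controls, but the limit set for that test overlooked that leaves express some of them, with PYK10 at 63.8 CPM in the 2-day control and 24.6 CPM at T0, which would hide a small share. The failure of 3 of the 10 to pass the count filter was known before, ESB1 shares most of its exons with another gene model, and PHT1;1, NRT2.1, RGF7 and LBD16, genes known from roots, were higher in the explant. A response to the wound treatment was not separated from root tissue, the part of the leaf, detachment or culture. With 1 library per group, differences between single samples stay open too.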
